A study of Homo sapiens with 44 samples.

How the data were processed

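The deposited values are log2 expression values made with RMA, per the submitters' processing notes; the version of RMA is not given in the sources used here. RNA from DLD-1 derivatives was hybridized to 44 Affymetrix HG-U133 Plus 2.0 arrays in 14 groups of line, dose and time. Each RNA was pooled from 3 plates, and each condition had 3 independent isolations, with 4 in the wild-type water groups at 8 h and 23 h. Batches and scan days are not given in the sources used here. The values ran from 2.77 to 14.8 over 54675 probe sets, and the median SD within groups was 0.127.

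Groups came from the sample labels. Of the probe sets, 41097 carried 1 gene symbol, 1801 several and 11777 none; 41043 were matched by Entrez ID to a current gene table, and 0 symbols changed. Each of 19775 genes was represented by its probe set with the highest mean. Genes whose highest group mean lay above the 30th percentile of all values (4.77) were tested, which left 16523. Some genes of the fixed lists were not analysed here.

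Linear models with 1 mean per group were fitted to all arrays in R 4.3.3 with limma 3.58.1 (input read with data.table, version 1.17.8), with empirical Bayes moderation (30 residual and 5.78 prior degrees of freedom). Tables were drawn as figures with matplotlib 3.10.9. The 17 comparisons were doxycycline against water in each line, dose and time (8), the high against the low dose at each time, and differences between responses: wild type minus mutant at both doses and times, wild type minus dnLEF-1, and 23 h minus 8 h in the wild-type and mutant lines. P values were adjusted within each comparison by Benjamini and Hochberg, and a gene passed at an adjusted p under 0.05. The comparisons, the lists, the filters, the named-gene rule and all other settings except those named below were chosen before the data were examined. No scaling was added to the deposited values.

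Lists of genes were fixed for Wnt targets, Wnt pathway components, enterocyte and secretory markers, G1 to S and mitotic genes, CDK inhibitors, p53 targets, MYC-regulated ribosome biogenesis, glycolysis, oxidative phosphorylation, the amino acid response (ATF4), endoplasmic reticulum stress, cholesterol synthesis, interferon, BMP and Notch signalling, hypoxia, immediate early genes, NF-kappaB inflammation, apoptosis, mesenchymal and immune cell markers, and housekeeping genes, 23 in all. They were tested against the other genes with camera at a preset correlation of 0.01, and again with the correlation estimated from the data. P values were adjusted over the 23 lists. Lists of heat shock genes and NRF2 targets were written after the comparisons above had been seen.

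Genes named in the text were a fixed panel (AXIN2, LGR5, ASCL2, SP5, NKD1, MYC, CCND1, CDKN1A, CDKN1B and PDK1), LEF1, and genes chosen by rule. The rule took up to 8 genes per direction with the largest change in each comparison with water, among those that passed with all treated arrays outside the range of the controls. It took up to 5 per direction for comparisons of responses or doses, and up to 4 members of each list with the smallest p. Further list members were named as examples after their values were seen.

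Whether replicate numbers paired the arrays was checked by correlating residuals: in the mutant line at both times, the dnLEF-1 line and the mock line all 3 own-number pairs correlated best (lowest r 0.142, 0.133, 0.356 and 0.274), and all these r lay above 0.1; the wild-type line did not meet both conditions at any dose or time. A fit with replicate number as a block was therefore run as an alternative. The other settings tried were no filter, a filter at the 50th percentile (5.91), quantile normalization, moderation with a trend and robust prior, the mean of all probe sets of a gene, every probe set, a 1.5-fold minimum, the compared groups alone, subtraction of the mock response, fry for the lists, and leaving out each array in turn. Chosen after the data were seen were water replicate 1 as the only control of the low dose (a lone array, assumed to vary like the other groups), water replicates 2 to 4 as the controls, and each dose against its nearest water arrays.

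The method was tested on simulated data with the same groups. The noise was drawn independently for each gene and array, without the replicate pairing or the differences among water arrays of the real data. The rates below therefore need not hold for the real arrays. For the high dose at 23 h it recovered 92% of genes changed by 0.5 and 100% of those changed by 1 or 2 on the log2 scale, with 8 false calls among 16523 genes. For the mutant line at 23 h the shares were 78%, 100% and 100% with 11 false calls, and for the difference between these responses 48%, 100% and 100% with 10. The number of arrays per group, 3 or 4, limits the precision.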

Results

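RNA was measured on 44 Affymetrix HG-U133 Plus 2.0 arrays, with values on the log2 scale, in derivatives of DLD-1, a human colon cancer line whose mutant APC leaves Wnt signalling constantly active. The lines carry a tetracycline-regulated transgene, so that doxycycline switches on a dominant-negative form of a Wnt transcription factor that cannot bind beta-catenin. One line (D7p11) makes wild-type dnTCF-1E, a second (MT45) makes dnTCF-1E with 5 amino acid substitutions in the C-clamp, a DNA-binding domain of its E-tail, and another (T20) makes dnLEF-1. The mock line (DLD TR7) is the parental line, which has the Tet regulator and no transgene. The wild-type line was given 1 µg/ml (high dose), 0.0006 µg/ml (low dose) or water, and the other lines 1 µg/ml or water. The wild-type and mutant lines were sampled at 8 h and 23 h, the dnLEF-1 and mock lines at 23 h alone. Each of the 14 groups held 3 arrays, except the wild-type water groups at 8 h and at 23 h with 4 each. Changes are log2 differences with the standard error (± SE) of the fit, and group levels are means with their SD. Unless stated otherwise, p values are limma's, adjusted over 16523 genes. The number of arrays limits the precision.

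LEF1, which encodes LEF-1, has 3 probe sets, and which of them cover the transgene was not tested. One rose in the dnLEF-1 line from 8.84 ± 0.23 (SD, n = 3) with water to 11.87 ± 0.33 (SD, n = 3) with doxycycline, an 8.19-fold rise (adjusted p = 4.5e-18, limma, adjusted over all 54675 probe sets). Without doxycycline this level was already above the mock line, which stood at 6.56 ± 0.23 (SD, n = 3). The wild-type dnTCF-1E line, which has no LEF-1 transgene, also stood above the mock line there, at 7.75 ± 0.20 (SD, n = 4) with water at 23 h. The probe set of LEF1 with the highest mean, used below, differed by -0.19 ± 0.12 in the dnLEF-1 line (adjusted p = 0.84). No probe set carried TCF7, the gene of TCF-1, as its only symbol, so neither dnTCF-1E transgene was followed here. The amounts made by the wild-type and mutant lines were not compared.

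**Figure D1:**
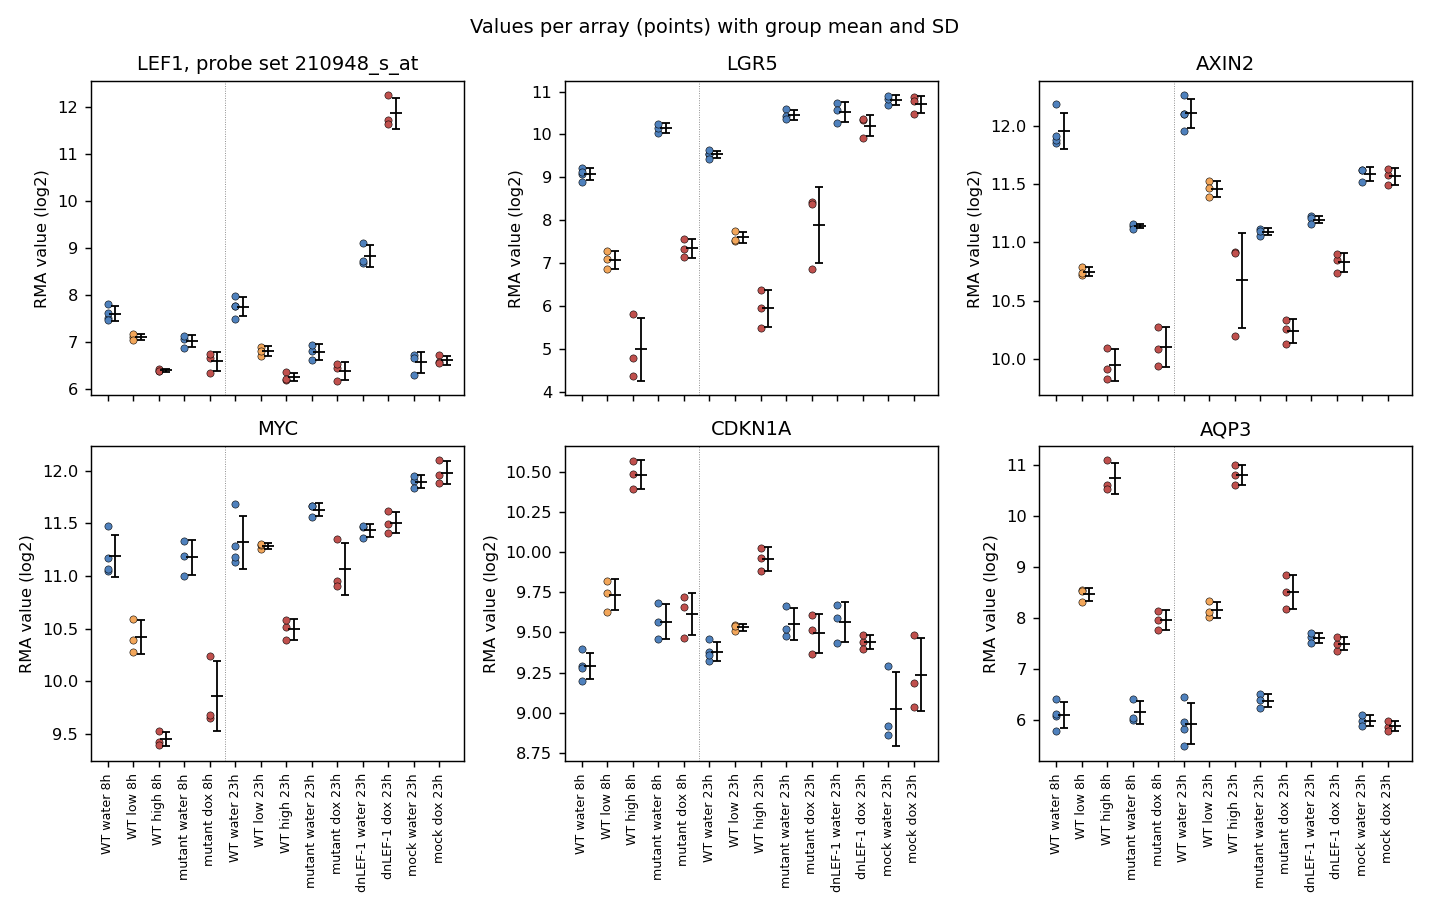
RMA values (log2) of 6 probe sets in every array, grouped by line, dose and time, with water in blue, the low dose in orange and 1 µg/ml in red; the black mark beside each group is its mean and SD. The LEF1 probe set shown stands at 11.87 in the induced dnLEF-1 arrays, and CDKN1A reaches 10.48 in the wild-type line at the high dose and 8 h.

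The first question was what changes within 8 h when wild-type dnTCF-1E is switched on. The mock line was not sampled at 8 h, so effects of doxycycline itself were not measured at that time in any line. LGR5, the R-spondin receptor of intestinal stem cells, dropped from 9.07 ± 0.14 (SD, n = 4) to 4.99 ± 0.74 (SD, n = 3), a change of -4.08 ± 0.25 (adjusted p = 2.2e-15), with induced arrays at 4.37, 5.81 and 4.78, near the low-signal limit of 4.77. TNFRSF19, a receptor of the TNF family, changed by -3.76 ± 0.21. AXIN2, a scaffold of the beta-catenin destruction complex and a feedback target of the pathway, went from 11.95 ± 0.15 (SD, n = 4) to 9.95 ± 0.14 (SD, n = 3). MYC changed by -1.74 ± 0.12 and ASCL2, a transcription factor of intestinal stem cells, by -1.66 ± 0.11. Other large falls were PRR9 at -3.23, SLC6A14, an amino acid transporter, at -2.81, the antisense RNA HECW2-AS1 at -2.78, the receptor tyrosine kinase KIT at -2.66, DOCK4 at -2.53 and the Wnt corepressor TLE4 at -2.42. SLC6A14 and HECW2-AS1 reached 4.29 and 3.19, below the low-signal limit. The largest rises were HSPA6, a stress-inducible HSP70, at +4.82 ± 0.23, and AQP3, a water and glycerol channel, at +4.65 ± 0.16. CRYAB, a small heat shock protein, rose by 2.52, the stress-induced mTORC1 inhibitor DDIT4 by 2.50, CLIC3 by 2.49, AHNAK2 by 2.29, the ERK phosphatase DUSP5 by 2.20 and IER5L by 2.16. In all, 2182 genes were higher and 2222 lower at an adjusted p under 0.05, and 976 of these 4404 passed 1.5-fold (366 higher and 610 lower). After quantile normalization 2467 were higher and 2154 lower, so the majority direction depended on scaling.

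Of 35 fixed Wnt target genes measured at 8 h, 20 fell, 3 rose and 12 did not pass, and the counts adjusted over the list alone were the same 20 and 3. The median was -0.76 (camera adjusted p = 1.6e-28; adjusted p = 1.2e-03 with an estimated correlation). ZNRF3 and RNF43, ligases that clear Wnt receptors, fell by 1.93 and 1.56, while cyclin D1, CCND1, rose by 0.52 ± 0.09, as did EPHB3 by 0.60. NKD1, a feedback inhibitor of the pathway, differed by -0.11 ± 0.08 (adjusted p = 0.38). Genes of ribosome biogenesis and nucleotide synthesis that MYC regulates moved together: 29 of 34 fell and 0 rose, or 32 lower when adjusted over the list alone. Their median was -0.50 (camera adjusted p = 1.1e-27; adjusted p = 2.4e-03 with an estimated correlation), with LYAR at -1.09, NOP16 at -1.04 and BYSL at -0.92.

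CDKN1A, the CDK inhibitor p21, rose at 8 h from 9.29 ± 0.08 (SD, n = 4) to 10.48 ± 0.09 (SD, n = 3), by 1.19 ± 0.09 (2.29-fold, adjusted p = 5.6e-13). Of 7 CDK inhibitor genes, 3 rose and 1 fell, over all genes and adjusted over the list alone. CDKN1C rose by 2.00 and CDKN2D by 0.73, whereas CDKN3, a phosphatase in the same list, changed by -0.67 (list median +0.30, camera adjusted p = 0.011; adjusted p = 0.23 with an estimated correlation). CDKN1B, which encodes p27, differed by -0.12 ± 0.09 (adjusted p = 0.38). Among 45 genes of the G1 to S transition 15 fell and 2 rose, by both adjustments, led by the primase subunit PRIM1 at -0.89 (median -0.13, camera adjusted p = 4.3e-03; adjusted p = 0.70 with an estimated correlation). Immediate early genes had 14 of 24 higher and 5 lower, by both adjustments (median +0.46, camera adjusted p = 2.5e-05; adjusted p = 0.23 with an estimated correlation), with DUSP1 at +1.42, FOS at +1.16 and JUN at +1.00. Hypoxia genes had 10 of 16 higher and 4 lower, by both adjustments, including NDRG1 at +1.42 and VEGFA at +0.90 (median +0.35, camera adjusted p = 4.3e-03; adjusted p = 0.23 with an estimated correlation). PDK1, a pyruvate dehydrogenase kinase in that list and among the glycolysis genes, fell by 0.59 ± 0.14.

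**Figure D2:**
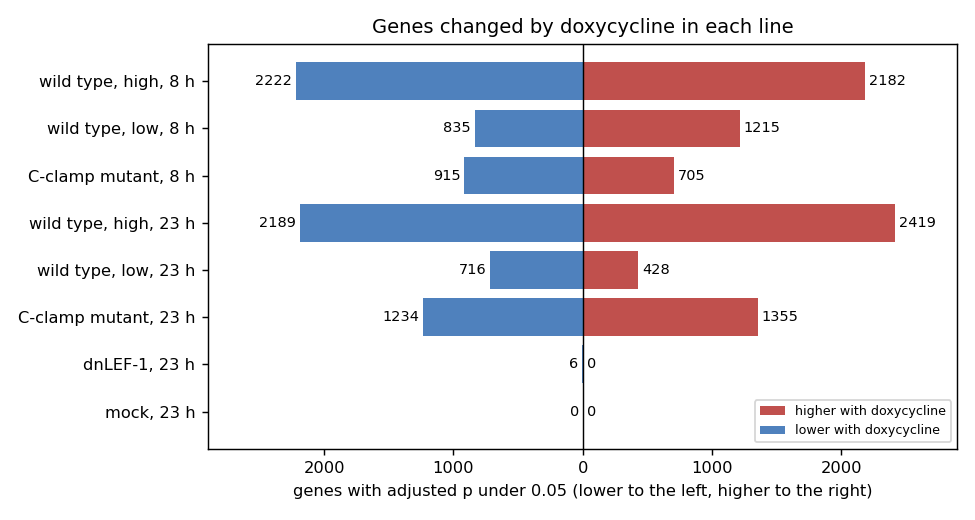
Number of genes higher (red, right) and lower (blue, left) with doxycycline than with water at an adjusted p under 0.05, by line, dose and time. The wild-type line at the high dose had 4404 genes at 8 h and 4608 at 23 h, the dnLEF-1 line 6 and the mock line 0.

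The next question was how much of this needs an intact C-clamp. In the mutant line at 8 h, 705 genes were higher and 915 lower, 1620 together. With replicate number as a block, which paired the arrays of this line, 981 were higher and 1207 lower (2188). The same block gave 4991 in the wild-type line at the high dose and 8 h. After quantile normalization of all arrays 959 were higher and 825 lower, so which direction held the majority depended on scaling. TNFRSF19 at -3.23 ± 0.23, LGR5 at -2.80 ± 0.27 and HECW2-AS1 at -2.56 ± 0.20 fell most, followed by the phosphatase PTPRR at -2.17, SEMA3C at -2.08 and TGFB2 at -1.94. HECW2-AS1 and SEMA3C reached 3.22 and 4.73, below the low-signal limit. MYC fell by 1.32 ± 0.13, from 11.18 ± 0.17 (SD, n = 3) to 9.86 ± 0.33 (SD, n = 3). AXIN2 fell by 1.03 ± 0.11 and ASCL2 by 0.86 ± 0.11. AQP3 rose by 1.81 ± 0.18, the bile acid transporter subunit SLC51B by 1.30, MYADM by 1.20, the epithelial transcription factor ELF3 by 1.16 and HSPA6 by 1.11. CDKN1A differed by +0.05 ± 0.10 (adjusted p = 0.87), with 9.61 ± 0.13 (SD, n = 3) against 9.57 ± 0.11 (SD, n = 3), whereas CDKN1B fell by 0.53 ± 0.10 (adjusted p = 2.6e-04).

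Wnt targets in the mutant line at 8 h had 16 of 35 lower and 1 higher, by both adjustments (median -0.27, camera adjusted p = 6.1e-23; adjusted p = 1.5e-03 with an estimated correlation). The guanine nucleotide exchange factor VAV3 fell by 1.85 ± 0.16. The MYC-regulated list had 21 of 34 lower and 0 higher, 27 lower adjusted over the list alone (median -0.31, camera adjusted p = 2.4e-25; adjusted p = 2.4e-03 with an estimated correlation). Mitotic genes had 4 of 40 higher and 0 lower, 7 higher adjusted over the list alone (camera adjusted p = 1.7e-03; adjusted p = 0.73 with an estimated correlation). Amino acid response genes had 5 of 34 higher and 1 lower (7 and 1 adjusted over the list alone), with camera adjusted p = 0.013 and adjusted p = 0.73 with an estimated correlation. There were no mock arrays at 8 h to subtract from that list. Hypoxia genes had 4 of 16 higher and 2 lower (5 and 2 adjusted over the list alone; camera adjusted p = 0.018; adjusted p = 0.37 with an estimated correlation). Immediate early genes had 9 of 24 higher and 5 lower by both adjustments (camera adjusted p = 0.045; adjusted p = 0.62 with an estimated correlation).

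The high-dose wild-type response at 8 h was then set directly against the mutant response, each from 1 clone. The difference passed for 604 genes, 251 more positive and 353 more negative in the wild-type line. CDKN1A differed by 1.15 ± 0.13 (adjusted p = 2.4e-07), HSPA6 by 3.71 ± 0.34, AQP3 by 2.84 ± 0.24 and CRYAB by 2.28 ± 0.17. SLC6A14 differed by -2.83 ± 0.30, TLE4 by -2.21 ± 0.26, the proteasome assembly factor PAAF1 by -2.10 ± 0.14, the hyaluronan synthase HAS2 by -1.90 and the Frizzled ligand NDP by -1.77. SLC6A14, HAS2 and NDP stood at 3.54, 3.89 and 4.40 in the mutant water arrays, below the low-signal limit of 4.77, so that line had little signal to lose. Among Wnt targets, AXIN2 differed by -0.97 ± 0.16 (adjusted p = 7.8e-05), LEF1 by -0.82 ± 0.16 and ASCL2 by -0.80 ± 0.16. AXIN2 started lower in the mutant water arrays (11.14, 11.15 and 11.12) than in the wild-type ones (11.85, 11.87, 11.91 and 12.18). With doxycycline the mutant arrays stood at 10.09, 9.94 and 10.28 and the wild-type ones at 9.83, 10.10 and 9.91. The AXIN2 difference thus lay mostly between the water arrays. The induced arrays of ASCL2 did lie apart, at 8.87, 8.84 and 8.91 (wild type) against 9.32, 9.34 and 9.32. Its water arrays also started lower in the mutant line, at 10.17, 10.22 and 10.16 against 10.57, 10.72, 10.37 and 10.46. LEF1 stood at 9.51 ± 0.07 (SD, n = 3) in the mutant and 10.11 ± 0.21 (SD, n = 4) in the wild-type water arrays. With doxycycline it stood at 9.02 ± 0.13 and 8.79 ± 0.02 (SD, n = 3 in each). The LEF1 difference thus also lay mostly between the water arrays. MYC, at -0.42 ± 0.18 (adjusted p = 0.26), CCND1 at +0.18 ± 0.14 and CDKN1B at +0.41 ± 0.14 did not pass. LGR5 at -1.28 ± 0.36 (adjusted p = 0.038) and SP5 at -0.57 ± 0.17 (adjusted p = 0.044) passed narrowly. LGR5 lost its call without high-dose replicates 1 (adjusted p = 0.19) or 3 (0.12), wild-type water replicates 1 (0.072), 2 (0.058) or 3 (0.059), induced mutant replicates 2 (0.065) or 3 (0.12), or mutant water replicates 1 (0.093), 2 (0.078) or 3 (0.058). It also ended with a trend and robust prior (0.059) and with the mean of all probe sets, which gave LGR5 -0.58 (adjusted p = 0.44). SP5 lost its call without high-dose replicates 1 (0.12), 2 (0.058) or 3 (0.075), wild-type water replicates 1 (0.080) or 2 (0.093), induced mutant replicates 1 (0.12) or 2 (0.12), mutant water replicates 1 (0.10), 2 (0.079) or 3 (0.072), with replicate number as a block (0.059) and with no filter (0.051). Of the 35 Wnt targets 11 were more negative and 2 more positive in the wild-type line, 16 and 2 adjusted over the list alone (median -0.38, camera adjusted p = 2.0e-09; adjusted p = 0.042 with an estimated correlation). The CDK inhibitors had 2 of 7 more positive and 1 more negative, 3 and 1 adjusted over the list alone (median +0.36, camera adjusted p = 4.2e-04; adjusted p = 0.042 with an estimated correlation). With replicate number as a block the difference passed for 938 genes.

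**Figure D3:**
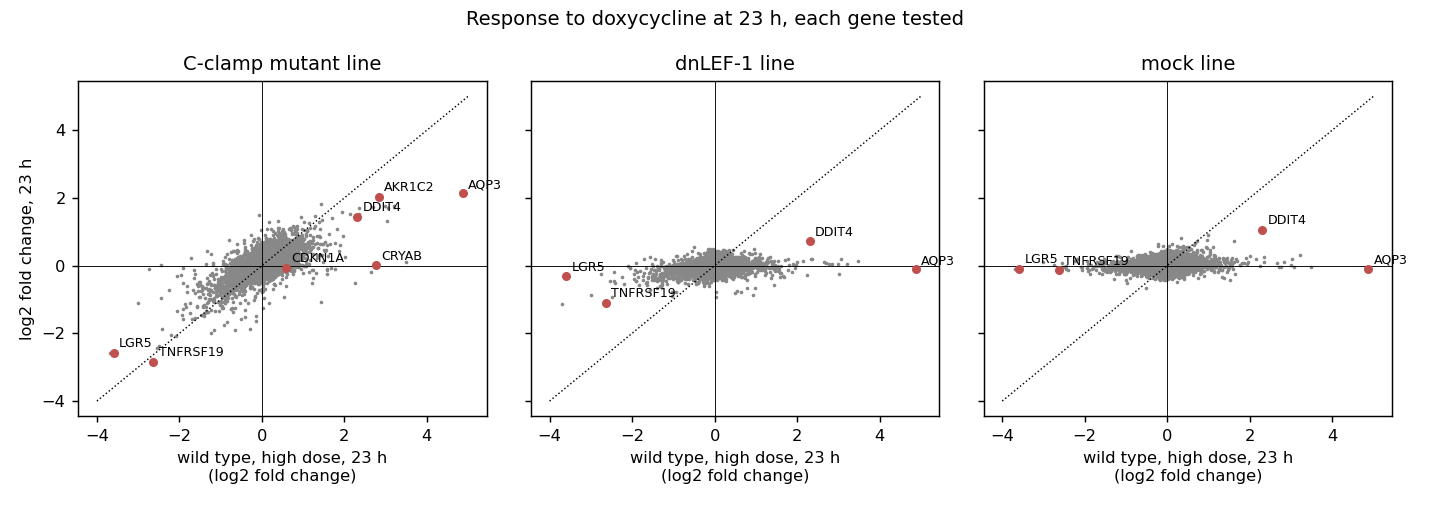
Log2 fold change of every gene tested at 23 h in the wild-type line at the high dose (x axis) against the mutant, dnLEF-1 and mock lines (y axis), with the line of equality dotted. In the mutant line AQP3 rose by 2.13 and CRYAB lay near 0, while in the dnLEF-1 and mock lines most genes lay near 0 on the y axis.

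At 23 h the high dose of the wild-type line left 2419 genes higher and 2189 lower, 4608 together, of which 898 passed 1.5-fold (426 higher and 472 lower). AQP3 rose by 4.87 ± 0.16 (29.3-fold, adjusted p = 1.5e-22), the secreted ligand IGFL1 by 3.48 ± 0.13, AHNAK2 by 3.21, HSPA6 by 3.07, CLIC3 by 3.03, galectin 1 (LGALS1) by 2.99 and the aldo-keto reductase AKR1C2 by 2.84. HECW2-AS1, at 3.21 below the low-signal limit of 4.77 once induced, fell by 3.69 ± 0.18, with LGR5 at -3.59 ± 0.25, DOCK4 at -3.00, SLC6A14 at -2.74, TNFRSF19 at -2.63, the chemokine CXCL5 at -2.54, SEMA3C at -2.49 and the efflux pump ABCB1 at -2.45. CDKN1A rose by 0.58 ± 0.09, from 9.38 ± 0.06 (SD, n = 4) to 9.96 ± 0.07 (SD, n = 3). After the mock response was subtracted its rise was 0.36 (adjusted p = 0.066), which no longer passed. The same subtraction left 2174 genes, 1084 higher and 1090 lower. Any such subtraction adds the error of the mock arrays: the SE of the Wnt target mean went from 0.047 to 0.068. Fewer genes then pass even where doxycycline itself does nothing. SEMA3C and SLC6A14 also reached levels below that limit, at 4.55 and 4.68.

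Wnt targets at 23 h in that line had 20 of 35 lower and 4 higher, by both adjustments (median -0.43, camera adjusted p = 1.2e-14; adjusted p = 8.9e-03 with an estimated correlation), with AXIN2 at -1.43 ± 0.11, ASCL2 at -1.61 ± 0.11 and LEF1 at -1.57 ± 0.11. MYC stood at -0.82 and its list had 31 of 34 lower and 0 higher, 33 lower adjusted over the list alone (median -0.43, camera adjusted p = 9.0e-23; adjusted p = 7.3e-03 with an estimated correlation). G1 to S genes had 23 of 45 lower and 1 higher, 27 and 2 adjusted over the list alone, among them PCNA at -0.33 and MCM2 at -0.23 (camera adjusted p = 5.3e-05; adjusted p = 0.37 with an estimated correlation). Genes of cholesterol synthesis had 11 of 18 lower and 2 higher, by both adjustments, including MSMO1 at -1.05, SQLE at -1.02 and DHCR7 at -1.01 (median -0.33, camera adjusted p = 1.2e-06; adjusted p = 0.095 with an estimated correlation). Amino acid response genes had 20 of 34 higher and 1 lower, by both adjustments, with DDIT4 at +2.31 and the asparagine synthetase ASNS at +0.84 (median +0.31, camera adjusted p = 1.8e-04; adjusted p = 0.39 with an estimated correlation). After the mock response was subtracted that call was lost (adjusted p = 0.75). Interferon genes had 7 of 21 higher and 3 lower, 7 and 4 adjusted over the list alone, with OASL at +1.34, IFIT1 at +1.33 and OAS1 at -1.62 (camera adjusted p = 0.021; adjusted p = 0.39 with an estimated correlation; 0.077 after the mock response was subtracted). Hypoxia genes had 9 of 16 higher and 3 lower, by both adjustments (camera adjusted p = 0.011; adjusted p = 0.25 with an estimated correlation; 0.058 after the mock response was subtracted). Immediate early genes had 13 of 24 higher and 2 lower, 14 and 2 adjusted over the list alone, with FOS at +1.87 (camera adjusted p = 3.4e-04; adjusted p = 0.27 with an estimated correlation).

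In the mutant line at 23 h, 1355 genes were higher and 1234 lower, 2589 together, or 1635 without replicate 3 of its induced arrays. After the mock response was subtracted there were 640 (318 higher and 322 lower). With replicate number as a block 1717 were higher and 1483 lower (3200), against 5097 genes in the wild-type line at the high dose with that block. TNFRSF19 fell by 2.84 ± 0.23, followed by HECW2-AS1 and LGR5 at -2.57 each, CXCL5 at -2.44, SEMA3C at -2.38 and the guanylate-binding protein GBP3 at -1.98. HECW2-AS1 and SEMA3C reached 3.02 and 4.42, below the low-signal limit. AQP3 rose by 2.13 ± 0.18, AKR1C2 by 2.04, MXRA7 by 1.81, LGALS1 by 1.77 and AHNAK2 by 1.76. AXIN2 fell by 0.85 ± 0.11, MYC by 0.56 ± 0.13 and PDK1 by 1.10 ± 0.15, while CDKN1A differed by -0.06 ± 0.10 (adjusted p = 0.80). Wnt targets had 12 of 35 lower and 2 higher, 14 and 3 adjusted over the list alone (median -0.12, camera adjusted p = 2.0e-07; adjusted p = 0.13 with an estimated correlation). The MYC-regulated list had 27 of 34 lower and 0 higher, 30 lower adjusted over the list alone (median -0.34, camera adjusted p = 2.6e-21; adjusted p = 0.010 with an estimated correlation). Further lists were called with the preset correlation and lost with an estimated correlation. G1 to S genes had 16 of 45 lower and 0 higher, 22 lower adjusted over the list alone (camera adjusted p = 4.0e-06; adjusted p = 0.26 with an estimated correlation). Mitotic genes had 12 of 40 higher and 0 lower, 15 and 1 adjusted over the list alone, with CDC25C at +0.53 (camera adjusted p = 2.1e-04; adjusted p = 0.51 with an estimated correlation). Amino acid response genes had 13 of 34 higher, 16 adjusted over the list alone, and 0 lower (camera adjusted p = 5.5e-05; adjusted p = 0.35 with an estimated correlation; 0.79 after the mock response was subtracted). Cholesterol synthesis had 9 of 18 lower and 2 higher, by both adjustments (camera adjusted p = 4.8e-05; adjusted p = 0.16 with an estimated correlation; 0.086 after the mock response was subtracted). Interferon genes had 8 of 21 higher and 2 lower, 11 and 2 adjusted over the list alone (camera adjusted p = 0.010; adjusted p = 0.17 with an estimated correlation; 0.072 after the mock response was subtracted). Hypoxia genes had 7 of 16 higher and 2 lower, 8 and 2 adjusted over the list alone (camera adjusted p = 2.3e-03; adjusted p = 0.16 with an estimated correlation). Immediate early genes had 7 of 24 higher and 3 lower, 7 and 4 adjusted over the list alone, without a call (camera adjusted p = 0.083), but with replicate number as a block they reached adjusted p = 0.016.

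The wild-type response exceeded the mutant response at 23 h for IGFL1 by 3.37 ± 0.19 (adjusted p = 4.6e-15), the small GTPase RRAD by 2.85 ± 0.28, CRYAB by 2.76 ± 0.17, AQP3 by 2.74 ± 0.24 and CDKN1A by 0.64 ± 0.13 (adjusted p = 2.6e-03). SLC6A14 differed by -2.63 ± 0.30, ABCB1 by -2.47 ± 0.30, PAAF1 by -1.94 ± 0.14 and DOCK4 by -1.90 ± 0.29. SLC6A14 and ABCB1 stood below the low-signal limit in the mutant water arrays, at 3.68 and 4.30, and DOCK4 reached 4.30 in the induced ones, so that line had little signal to lose. LEF1 differed by -1.04 ± 0.16, SP5 by -0.81 ± 0.17, ASCL2 by -0.81 ± 0.16 and AXIN2 by -0.58 ± 0.16 (adjusted p = 0.022), whereas LGR5 at -1.02 ± 0.36 (adjusted p = 0.12) and MYC at -0.26 ± 0.18 (adjusted p = 0.55) did not pass. AXIN2 again started lower in the mutant water arrays (11.1 in each) than in the wild-type ones (12.0, 12.1, 12.3 and 12.1). With doxycycline the mutant arrays stood at 10.3, 10.3 and 10.1 and the wild-type ones at 10.2, 10.9 and 10.9. The AXIN2 level reached in the mutant line was thus not higher. ASCL2 also started lower in the mutant water arrays (10.08, 10.32 and 10.15) than in the wild-type ones (10.70, 10.76, 11.05 and 10.98). Its induced arrays overlapped, at 9.46, 9.48 and 9.19 (mutant) and 8.98, 9.46 and 9.34 (wild type). LEF1 stood at 9.53 ± 0.10 (SD, n = 3) and 10.38 ± 0.09 (SD, n = 4) in these water arrays. With doxycycline it stood at 9.00 ± 0.15 and 8.80 ± 0.33 (SD, n = 3 in each). Both differences thus lay mostly between the water arrays. The call for AXIN2 ended without replicate 1 of the high dose (adjusted p = 0.14), replicate 3 of the wild-type water arrays (0.055) or replicate 2 of the induced mutant (0.072), and with the compared groups fitted alone (0.18), where that for SP5 at -0.81 also ended (0.063). LGR5 passed at -1.53 without replicate 3 of the induced mutant (adjusted p = 1.8e-03). In total 331 genes were more positive and 319 more negative, 650 together, or 415 without replicate 1 of the high dose and 987 with replicate number as a block, where 476 were more positive and 511 more negative. Wnt targets had 10 of 35 more negative and 1 more positive, 12 and 2 adjusted over the list alone (camera adjusted p = 2.7e-05; adjusted p = 0.19 with an estimated correlation). Enterocyte markers had 4 of 29 more positive and 2 more negative, 9 and 2 adjusted over the list alone (median +0.23, camera adjusted p = 4.5e-03; adjusted p = 0.055 with an estimated correlation).

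**Figure D4:**
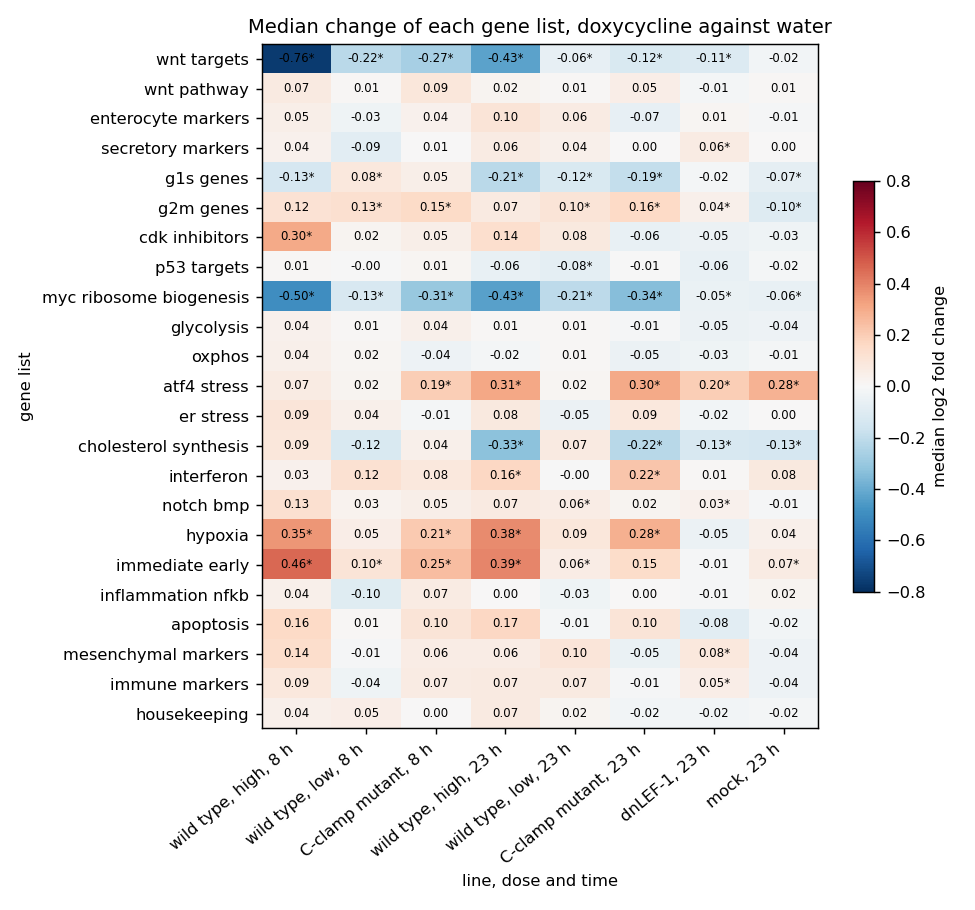
Median log2 fold change of each of the 23 fixed gene lists for doxycycline against water in 8 comparisons, with an asterisk where camera with the preset correlation gave an adjusted p under 0.05. Wnt targets stand at -0.76 and the MYC-regulated list at -0.50 in the wild-type line at the high dose and 8 h.

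The low dose asked what a small amount of wild-type dnTCF-1E does. At 8 h HECW2-AS1 fell, at -2.46, as did SLC6A14 at -2.16, LGR5 at -1.99 ± 0.25, PRR9 at -1.79, TLE4 at -1.67, the nuclear receptor RORA at -1.66 and AXIN2 at -1.21 ± 0.11, from 11.95 ± 0.15 (SD, n = 4) to 10.75 ± 0.04 (SD, n = 3). HSPA6 rose by 3.27 ± 0.23, AQP3 by 2.37 ± 0.16 and CDKN1A by 0.44 ± 0.09 (adjusted p = 1.1e-03). At 23 h HECW2-AS1 stood at -3.20, SEMA3C at -2.10, DOCK4 at -1.99, LGR5 at -1.94 ± 0.25, ASCL2 at -1.28 ± 0.11 and AXIN2 at -0.65 ± 0.11. HECW2-AS1 reached 3.52 and 3.71 at these times, below the low-signal limit. SCEL, a protein of the cornified envelope, rose by 2.54 ± 0.14, AQP3 by 2.23, AKR1C2 by 2.00 and AKR1C1 by 1.82. CDKN1A at +0.15 ± 0.09 (adjusted p = 0.36) and MYC at -0.03 ± 0.12 did not pass at 23 h. Counts were 1215 higher and 835 lower at 8 h (2050) and 428 higher and 716 lower at 23 h (1144). The majority direction at 8 h turned at 1.5-fold (94 higher and 115 lower) and was nearly lost after quantile normalization (1065 and 1012). Subtracting the mock response, measured at 1 µg/ml, left 208 genes at 23 h. Replicate 1 of the water arrays stood apart at both times, nearer to the low-dose arrays (root mean square distances 0.221 at 8 h and 0.223 at 23 h) than to the other water arrays (0.236 and 0.229). With it as the only control, a setting chosen after the data were seen, 222 genes passed at 8 h, 79 higher and 143 lower, so the direction turned there too, and 186 at 23 h. AQP3, LGR5 and AXIN2 still passed at 8 h in that setting, but at 23 h AXIN2 at -0.50 (adjusted p = 0.15) did not. Leaving out single arrays moved the count at 8 h to 1292, 1148 and 1191 without low-dose replicates 1, 2 and 3, and to 1365, 1237 and 3017 without water replicates 2, 4 and 1. At 23 h it was 738 and 681 without low-dose replicates 1 and 3, and 1717 without water replicate 1.

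Wnt targets at the low dose had 18 of 35 lower and 1 higher at 8 h by both adjustments (median -0.22, camera adjusted p = 8.6e-20; adjusted p = 2.3e-03 with an estimated correlation). At 23 h they had 15 lower and 0 higher, 15 and 1 adjusted over the list alone (median -0.06, camera adjusted p = 3.3e-08; adjusted p = 0.088 with an estimated correlation). The MYC-regulated list had 11 of 34 lower at 8 h, 12 adjusted over the list alone (camera adjusted p = 1.8e-07; adjusted p = 0.37 with an estimated correlation), and 17 lower at 23 h, 21 adjusted over the list alone (camera adjusted p = 9.6e-15; adjusted p = 0.055 with an estimated correlation). At 8 h G1 to S genes had 8 of 45 higher and 0 lower, 11 adjusted over the list alone (camera adjusted p = 0.012; adjusted p = 0.74 with an estimated correlation). That direction was the opposite of the 23 h count of 4 lower and 0 higher, 8 lower adjusted over the list alone (camera adjusted p = 2.4e-05; adjusted p = 0.48 with an estimated correlation). BMP and Notch genes at 23 h had 4 of 25 higher and 0 lower by both adjustments, with BMP2 at +1.32, HES1 at +0.83 and ID1 at +0.80 (camera adjusted p = 0.012; adjusted p = 0.15 with an estimated correlation). The p53 targets had 4 of 25 lower and 0 higher at 23 h, 4 and 1 adjusted over the list alone (camera adjusted p = 0.044; adjusted p = 0.44 with an estimated correlation). With water replicate 1 as the only control BMP2 stood at +0.90 (adjusted p = 0.052).

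Set directly against the low dose, the high dose at 8 h gave lower LGR5 by -2.09 ± 0.27, TNFRSF19 by -2.47 ± 0.23 and MYC by -0.97 ± 0.13, and higher AQP3 by 2.28 ± 0.18, CRYAB by 2.25 ± 0.13 and CDKN1A by 0.75 ± 0.10. At 23 h IGFL1 was higher by 3.35 ± 0.14, HSPA6 by 2.86 ± 0.25, AQP3 by 2.65 ± 0.18 and RRAD by 2.14, and LGR5 differed by -1.66 ± 0.27. The doses differed at 2100 genes higher and 2490 lower with the high dose at 8 h (4590; 2458 and 2121 after quantile normalization, so the majority direction depended on scaling), and at 1845 higher and 1228 lower at 23 h (3073). With each dose set against its nearest water arrays, a setting chosen after the data were seen, 181 and 209 genes passed, and CDKN1A at +0.62 (adjusted p = 0.056) and MYC at -0.59 (adjusted p = 0.21) no longer did at 8 h, nor LGR5 at -1.65 (adjusted p = 0.069) at 23 h. At 23 h the cholesterol list was lower with the high dose in 12 of 18 genes and higher in 1, 13 and 2 adjusted over the list alone (median -0.38, camera adjusted p = 3.9e-15; adjusted p = 0.016 with an estimated correlation), a list whose median was -0.13 in the mock line at 1 µg/ml.

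The low-dose wild-type response was also set against the mutant response, since both were weaker than the high-dose one. At 8 h 258 genes were more positive and 134 more negative (392), but quantile normalization gave 208 and 244, so the majority direction depended on scaling. HSPA6 differed by 2.16 ± 0.34, VAV3 by 1.79 ± 0.22, TNFRSF19 by 1.94 ± 0.31 and PTPRR by 1.90 ± 0.25, and TLE4 by -1.46 ± 0.26. TLE4 stood at -1.19 with water replicate 1 as the only control of the low dose, where its call ended. SLC6A14 differed by -2.17 ± 0.30, but at 3.54 in the mutant water arrays it had little signal to lose there. At 23 h 150 were more positive and 269 more negative (419), with MALL at +2.13 ± 0.22, annexin A1 (ANXA1) at +1.81 ± 0.21 and REG4, a secreted lectin, at +1.80 ± 0.34. Neither AXIN2, at -0.17 ± 0.16 and +0.20 ± 0.16, nor CDKN1A, at +0.40 ± 0.13 and +0.21 ± 0.13, passed at 8 h or 23 h. With water replicate 1 as the only control of the low dose 31 genes passed at 8 h and 72 at 23 h. Leaving out single arrays gave at 8 h 248, 156 and 167 without low-dose replicates 1, 2 and 3, and 1202, 242, 250 and 159 without wild-type water replicates 1 to 4. Without induced mutant replicates 1 and 2 it gave 170 and 237, and without mutant water replicates 2 and 3 it gave 205 and 153. At 23 h the counts were 259 without low-dose replicate 1, 732 without wild-type water replicate 1, 222 without induced mutant replicate 3 and 274 without mutant water replicate 2. At 23 h cholesterol genes were more positive in 7 of 18 and more negative in 1, 10 and 2 adjusted over the list alone (median +0.28, adjusted p = 0.036 with an estimated correlation), and enterocyte markers in 3 of 29 and 1, 4 and 1 adjusted over the list alone (median +0.17, adjusted p = 0.036 with an estimated correlation). The doxycycline dose differed along with the construct in this comparison, and the mock line at 1 µg/ml had a cholesterol synthesis median of -0.13.

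The dnLEF-1 line asked whether another dominant-negative LEF/TCF protein acts alike. Its water arrays already stood above those of the mock line in the LEF1 probe set that rose (8.84 against 6.56). An effect already present without doxycycline would not be seen in comparisons with these water arrays, so few calls do not show that dnLEF-1 is inactive. At 23 h 6 genes fell and 0 rose: HECW2-AS1 at -1.12 ± 0.20, the metallothionein MT1F at -0.81 ± 0.16, TCF4 at -0.77 ± 0.13, DPYSL3 at -0.58 ± 0.10, the virus receptor CXADR at -0.50 ± 0.07 and ZCCHC14 at -0.37 ± 0.07. TNFRSF19 stood at -1.10 ± 0.23 (adjusted p = 0.063), AXIN2 at -0.37 ± 0.11 (adjusted p = 0.37) and LGR5 at -0.32 ± 0.27 (adjusted p = 0.89). At an unadjusted p under 0.05 there were 1085 genes. With replicate number as a block 3 rose and 39 fell, and PDK1 at -0.50 passed (adjusted p = 0.036). The count was 1 without replicate 1 or 2 of the induced arrays or replicate 3 of the water arrays, 2 without water replicate 2, 14 without water replicate 1 and 15 without induced replicate 3. After the mock response was subtracted it was 0, by limma. With the compared groups fitted alone 6 genes passed, but 1 of them was among these 6: HECW2-AS1 (adjusted p = 0.098), TCF4 (0.22), DPYSL3 (0.51), CXADR (0.17) and ZCCHC14 (0.82) lost their calls. MT1F (0.068) and ZCCHC14 (0.18) lost theirs after quantile normalization, and ZCCHC14 also with the mean of all probe sets (0.42). No Wnt target passed over all genes and 5 were lower adjusted over the list alone (median -0.11, camera adjusted p = 7.1e-03; adjusted p = 0.25 with an estimated correlation; 0.066 after the mock response was subtracted). Other lists called there with 0 genes passing were lost with an estimated correlation, such as amino acid response genes at a median of +0.20 (camera adjusted p = 4.0e-09; adjusted p = 0.23 with an estimated correlation; 0.054 after the mock response was subtracted) and cholesterol synthesis at -0.13 (camera adjusted p = 2.7e-05; adjusted p = 0.15 with an estimated correlation; 0.93 after the mock response was subtracted). So were mesenchymal markers at +0.08 (camera adjusted p = 7.1e-03; adjusted p = 0.21 with an estimated correlation), secretory markers at +0.06 (0.017; adjusted p = 0.15 with an estimated correlation) and immune cell markers at +0.05 (0.027; adjusted p = 0.25 with an estimated correlation). The high-dose wild-type response differed from the dnLEF-1 response at 1390 genes more positive and 863 more negative, 2253 together. AQP3 differed by 4.99 ± 0.24, IGFL1 by 3.34, LGR5 by -3.28 ± 0.36, ASCL2 by -1.29 ± 0.16, MYC by -0.90 ± 0.18 and CDKN1A by 0.70 ± 0.13. Wnt targets (16 of 35 more negative, 3 more positive, 17 and 4 adjusted over the list alone) and the MYC-regulated list (21 of 34 and 0, 26 and 0 adjusted over the list alone) both differed, with adjusted p = 0.016 with an estimated correlation in each.

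The mock line showed what 1 µg/ml doxycycline does without a transgene at 23 h, the only time at which that line was sampled. With limma 0 genes passed, where 767 had an unadjusted p under 0.05. The count was 4 with replicate number as a block, 1 when every probe set was tested, 6 without water replicate 1 and 1 without water replicate 3. DDIT4 stood at +1.06, VLDLR at +0.89 and CDKN1A at +0.21 ± 0.10. The amino acid response list still stood apart from other genes: 0 of 34 passed over all genes, but 14 were higher adjusted over the list alone (median +0.28, camera adjusted p = 6.0e-25; adjusted p = 0.065 with an estimated correlation). Cholesterol synthesis had a median of -0.13 with 0 genes passing by either adjustment (camera adjusted p = 4.2e-06; adjusted p = 0.17 with an estimated correlation). Wnt targets had a median of -0.02 (camera adjusted p = 0.87), with AXIN2 at -0.02 ± 0.11 and LGR5 at -0.10 ± 0.27.

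Time was tested as the change of each response from 8 h to 23 h. In the wild-type line at the high dose 254 genes became more positive and 139 more negative, 393 together, or 246 without replicate 3 of the induced arrays at 23 h and 639 with replicate number as a block. AKR1C2 gained 2.30 ± 0.24, AKR1C1 2.26 ± 0.18, IGFL1 2.02 ± 0.18 and LGALS1 1.68 ± 0.23. FGFBP1 differed by -1.94 ± 0.24, HSPA6 by -1.75 ± 0.33 and INSIG1, a brake on sterol synthesis, by -1.66 ± 0.23, having risen by 0.77 at 8 h and fallen by 0.89 at 23 h. MYC recovered by 0.92 ± 0.17 (adjusted p = 1.3e-03) and CDKN1A lost 0.62, a difference of -0.62 ± 0.13 (adjusted p = 4.1e-03). Cholesterol genes became more negative in 9 of 18 and more positive in 0, 13 and 0 adjusted over the list alone (median -0.33, camera adjusted p = 2.3e-23; adjusted p = 8.4e-04 with an estimated correlation). In the mutant line 20 genes became more positive and 12 more negative, 32 together. They included AKR1C2 at +1.63 ± 0.26, AKR1C1 at +1.28 ± 0.19, SELENOM at +1.22 ± 0.18 and the decoy receptor IL1R2 at -1.09 ± 0.17. AKR1C2 and AKR1C1 lost their calls with the compared groups fitted alone (adjusted p = 0.062 each). That count was 17 without replicate 3 of the induced arrays and 15 without water replicate 1, both at 23 h, and 97 with replicate number as a block. There cholesterol genes were more negative in 1 of 18, 8 adjusted over the list alone with 1 more positive (median -0.30), and enterocyte markers in 0 of 29, 3 adjusted over the list alone (median -0.15), each with adjusted p = 0.048 with an estimated correlation.

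Responses were also compared across genes, which are not independent replicates. Across the 16523 genes Pearson's r between the high-dose wild-type and mutant responses was 0.700 at 8 h and 0.651 at 23 h. At 8 h both lines called 500 genes higher and 786 lower where 93.1 and 123 would be shared by chance, and 22 in opposite directions. At 23 h the shared calls were 889 higher and 940 lower, against 198 and 163 by chance, with 28 opposite. The correlation of the wild-type response with the dnLEF-1 response was 0.229 and with the mock response 0.146. High and low dose responses correlated at 0.516 at 8 h and 0.625 at 23 h, but they shared water arrays. In simulated groups without any change, sharing gave 0.429 and 0.428, values set by the array numbers that cannot be subtracted from the real ones. The covariance was 0.0325 at 8 h and 0.0371 at 23 h, against 0.0045 in the simulations at each time. With separate water arrays for each dose, in 6 ways of dividing them, r ran from 0.215 to 0.627 at 8 h and from 0.334 to 0.638 at 23 h. The 366 genes that rose at least 1.5-fold at 8 h in the wild-type line at the high dose had a median at 23 h of +0.35 in the mutant line, +0.17 at the low dose, -0.02 in the dnLEF-1 line and +0.04 in the mock line. The 610 that fell at least 1.5-fold had medians of -0.32, -0.25, -0.10 and -0.00.

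The remaining lists gave no call in the wild-type line at the high dose, here at 8 h and with counts adjusted over the list alone. Receptors and other components of the Wnt pathway had 7 of 33 higher and 5 lower, 7 and 5 adjusted over the list alone (camera adjusted p = 0.90), with a median of +0.07 and a mean of -0.03 and TLE4 lowest. Enterocyte markers had 3 of 29 higher and 2 lower, 3 and 2 adjusted over the list alone (camera adjusted p = 0.70), where the intestinal transcription factor CDX2 fell by 0.92 and EMP1 rose by 1.53. Secretory markers had 1 of 19 higher and 0 lower, 0 adjusted over the list alone (0.84). Mitotic genes had 6 of 40 higher and 3 lower, 5 and 3 adjusted over the list alone (0.35). The p53 targets had 3 of 25 higher and 5 lower, by both adjustments (camera adjusted p = 0.73), with PLK2 at -1.58, a median of +0.01 and a mean of -0.05. Glycolysis genes had 5 of 26 higher and 4 lower, 5 and 5 adjusted over the list alone (0.55), and oxidative phosphorylation 4 of 40 higher, 0 adjusted over the list alone, and 0 lower (0.35). Endoplasmic reticulum stress genes had 6 of 18 higher and 1 lower (0.33), and NF-kappaB inflammation genes 5 of 19 higher and 4 lower, 6 and 4 adjusted over the list alone (0.71), with a median of +0.04 and a mean of -0.00. Apoptosis genes had 6 of 18 higher and 2 lower, 7 and 2 adjusted over the list alone (0.27). BMP and Notch genes had 5 of 25 higher and 3 lower, 5 and 4 adjusted over the list alone (0.70), with JAG1 at -1.77. Mesenchymal markers had 2 of 15 higher (0.32), immune cell markers 3 of 15 higher (0.60) and housekeeping genes 2 of 12 higher and 1 lower (0.70), each by both adjustments. Each value in brackets is a camera adjusted p.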

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

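Of the tests below, the scaling and the baseline tests of the wild-type and mutant difference at 8 h were written before their results were seen; the same tests at 23 h and the tests on water replicate 1, on the mock line and on the number of clones were chosen only after.

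The low-dose response of the wild-type line rested on water arrays that were not alike. Against water replicate 1 alone the low dose gave 222 genes at 8 h, and 574, 383 and 1475 against replicates 2, 3 and 4 alone (186, and 762, 336 and 244, at 23 h), each lone control array being assumed to vary like the other groups. These counts restate the distance by which water replicate 1 was singled out, so a batch shared with the low-dose arrays stays open. An accidental induction of water replicate 1 was argued against: its Wnt target mean lay 0.0802 (8 h) and 0.0858 (23 h) above the other water arrays, where induction would lower it. Low doxycycline lowering Wnt targets met its test, since their mean in the low-dose arrays lay at -0.473 and -0.341 relative to that same array, the highest of the 4 in that mean, and at the least at -0.336 (replicate 3, 8 h) and -0.161 (replicate 2, 23 h) relative to the others. Chance could not be excluded for the counts, because 2 of 35 splits gave as many at 8 h (2050, highest other 2901, water replicates 2 to 4 against the rest) and 2 of 35 at 23 h (1144, highest other 1481), a structure among the samples.

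The amino acid response list at 23 h had a mean shift of 0.334 ± 0.104 (SE) in the mock line, where its call was lost with an estimated correlation (adjusted p = 0.065), and the high-dose wild-type line exceeded that by 0.0907 ± 0.143 (SE). An added effect of dnTCF-1E on that list cannot be told apart from 0 with 3 mock arrays per group. For cholesterol synthesis the mock line shifted by -0.135 ± 0.050 (SE), too little to be the whole of the wild-type shift of -0.382, and the difference of -0.247 ± 0.068 (SE) is consistent with an effect beyond doxycycline, as a hypothesis. With an estimated correlation the call for that list was lost in both lines (adjusted p = 0.095 in the wild-type and 0.17 in the mock line).

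The high-dose wild-type and mutant responses differed at 604 genes at 8 h and 650 at 23 h, by a test of the difference. If the mutant response were the wild-type one times a single factor (0.649 at 8 h, 0.722 at 23 h), scaling would remove the differences. At 23 h 419 genes still differed, 356 of them among the 650, which argued against that factor as the whole cause; at 8 h 203 did, 177 of them among the 604, and 22 of the 604 moved in opposite directions, so it stays open only for genes that no longer differed. The mutant response went beyond the scaled wild-type one in 153 of the 203 and 352 of the 419, as for VAV3 at 1.67 (8 h). CDKN1A, at 0.73 after scaling at 8 h (adjusted p = 1.2e-04), and TLE4, at -1.37 (adjusted p = 1.7e-04), were among the rest of the 203. AXIN2, at -0.27 (adjusted p = 0.57), was not among the 203. Another starting level as the cause of most of these differences missed its test. Only 6.79% of the 604 (1.56% of all genes) and 13.2% of the 650 (1.88%) lay 1 or more apart between the water controls. That test did not count smaller gaps, such as those of AXIN2 and LEF1 at 8 h and of ASCL2 and LEF1 at 23 h. Both shares exceeded those of all genes. Another starting level therefore stays open. With 1 clone per construct, a difference between clones cannot be told apart from the C-clamp.

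Single genes also differed between these responses at 8 h (AXIN2 -0.97, LGR5 -1.28, ASCL2 -0.80, SP5 -0.57, CDKN1A 1.15) and at 23 h (AXIN2 -0.58, ASCL2 -0.81, SP5 -0.81, CDKN1A 0.64). The differences of AXIN2 at both times and of ASCL2 at 23 h lay mostly between the water arrays. List medians differed at 8 h for Wnt targets (-0.38) and CDK inhibitors (0.36). The low-dose response differed from the mutant response at 392 genes at 8 h and 419 at 23 h, with medians of 0.17 for enterocyte markers and 0.28 for cholesterol synthesis at 23 h; the doxycycline dose differs there too. The high-dose response differed from the dnLEF-1 response at 2253 genes, with medians of -0.33 for Wnt targets and -0.38 for the MYC-regulated list. Between the times 393 genes differed in the wild-type line (cholesterol synthesis -0.33) and 32 in the mutant line (enterocyte markers -0.15, cholesterol synthesis -0.30).

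Regrouping the arrays tested these counts. For the wild-type line at the high dose 1 of 35 splits, the real one, gave as many genes at 8 h (4404, highest other 3290). The same held for 1 of 35 at 23 h (4608, highest other 2914). That is the smallest share that 35 splits can give, and regrouping cannot tell a batch from doxycycline. The water arrays were also those of the low-dose comparison, so chance is not called excluded here. For differences of responses 100 splits were used, the real one and others drawn at random from those possible, without keeping replicate numbers together. The real split alone gave as many genes for wild type minus mutant at the high dose (604 against 196 and 650 against 168), wild type minus dnLEF-1 (2253 against 1092), and 23 h minus 8 h in the wild-type (393 against 163) and mutant lines (32 against 2). It also did so at the low dose (392 against 13 and 419 against 246). That comparison used the water arrays for which chance could not be excluded above, so it is not excluded there either. Comparisons of 3 with 3 arrays have 10 splits, too few for a share under 0.05: the mutant line at 8 h (1620, highest other 0) and 23 h (2589, highest other 0), the high against the low dose (4590 and 3073, highest other 0 in both), the dnLEF-1 line (6, highest other 13) and the mock line (0, highest other 29).

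Some water arrays lay far from the other 3 of their group, 5 of 66 values tested, where chance gives about 1 in 20. They were AXIN2 at 12.18 and the interferon list at 7.73 in replicate 4 at 8 h, the immediate early list at 8.93 in replicate 1 at 8 h, the Wnt pathway list at 8.38 in replicate 1 at 23 h, and the housekeeping list at 11.97 in replicate 2 at 23 h. Probe sets without a single gene symbol, outside the comparisons of the report, also carried signal: of 8222 tested, 847 passed at the high dose and 8 h, 528 at the low dose and 8 h, 211 in the mutant line at 8 h, 825, 203 and 316 in the same order at 23 h, 3 in the dnLEF-1 line and, with limma, 0 in the mock line.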

How the results depend on the processing

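Water replicate 1 as the only control, water replicates 2 to 4 as controls, and each dose against its nearest water arrays were chosen only after the data were seen. Of 6161 values of 370 named-gene results under the alternatives, 5955 kept direction and side of the threshold, 188 became weaker, 17 stronger and 1 reversed: LEF1 in the dnLEF-1 line was 0.92 as the mean of all its probe sets, of which 1 rose, by 3.03. Of 1104 list values 964 kept theirs, 105 became weaker and 35 stronger. Of 318 counts 232 stayed within 1.5 times and 86 moved. Testing every probe set, which counts a gene more than once, gave 8259 (high dose 8 h), 4158 (low dose 8 h), 2619 (mutant 8 h), 8419, 2070 and 4031 (the same at 23 h), 19 (dnLEF-1), 1 (mock), 755 (low dose minus mutant 8 h), and 9287 and 5989 (high against low dose). A 1.5-fold minimum, stricter by construction, gave 976, 209, 320, 898, 175, 496 and 3 for the first 7 of these comparisons, 285 and 340 for high dose minus mutant, 158 and 218 for low dose minus mutant, 656 and 511 for high against low dose, 784 for wild type minus dnLEF-1, and 161 for wild-type time. Fitting the compared groups alone, with fewer arrays, gave 1149 and 565 (low dose), 329 (high dose minus mutant 23 h), 1469 (minus dnLEF-1) and 164 (wild-type time). Replicate number as a block gave 42 (dnLEF-1), 4 (mock), 938 and 987 (high dose minus mutant), 746 (low dose minus mutant 23 h), 639 and 97 (wild-type and mutant time). Subtracting the mock response gave 2174, 208, 640 and 0 (high, low, mutant and dnLEF-1), although the mock line was given the high dose. This subtraction adds the error of the mock arrays, which by itself lowers the counts. A stricter filter gave 10 and the mean of probe sets 11 for dnLEF-1. Water replicate 1 as the only control gave 222 and 186 (low dose) and 31 and 72 (low dose minus mutant), and nearest water arrays 181 and 209 (high against low dose). Apart from constructions named here, the cause was not tested. Leaving out 1 array gave 1148 to 3017 and 681 to 1717 (low dose, 8 h and 23 h), 1635 to 2345 (mutant 23 h), 1 to 15 (dnLEF-1), 0 to 6 (mock), 415 to 669 (high dose minus mutant 23 h), 153 to 1202 and 222 to 732 (low dose minus mutant), 246 to 413 and 15 to 44 (wild-type and mutant time). Signal near background limits genes of low expression; the filter removed a gene only where its highest group mean was low, so single groups near background stayed in.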

Other observations

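The heat shock and NRF2 target lists below were written and tested only after the comparisons of the report had been seen, and all values here are given without an explanation.

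Both lists hold genes already seen among the largest rises (HSPA6 and CRYAB, AKR1C1 and AKR1C2), so a test on the same arrays partly restates them and no p is given. Of 22 heat shock genes 15 rose and 0 fell in the wild-type line at the high dose and 8 h (median +0.43), with HSPA6 at +4.82, CRYAB at +2.52 and SERPINH1 at +2.08. At 23 h 7 rose and 5 fell (median +0.06). In the mutant line at 8 h 4 rose and 0 fell (median +0.10), and in the mock line 0 passed with limma (median -0.10). The high-dose response exceeded the mutant response in 7 and was below it in 0 at 8 h, and in 3 and 0 at 23 h (medians +0.30 and +0.03). Among 20 NRF2 targets 10 rose and 1 fell at the high dose and 23 h (median +0.26), with AKR1C2 at +2.84 and AKR1C3 at +1.94. At the low dose and 23 h 7 rose and 0 fell (median +0.22), in the mutant line 6 rose and 2 fell (median +0.05), and in the dnLEF-1 and mock lines 0 passed with limma (medians -0.03 and +0.03).

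The dnLEF-1 line differed from the mock line before induction: LEF1, by the probe set that rose with doxycycline, stood at 8.84 ± 0.23 (SD, n = 3) with water against 6.56 ± 0.23 (SD, n = 3). With water at 23 h the wild-type line stood at 7.75 ± 0.20 (SD, n = 4) and the mutant line at 6.79 ± 0.16 (SD, n = 3). Whether the gap came from the transgene or from other differences between the lines was not tested.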
